A study of Mus musculus with 8 samples.

How the data were processed

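H3K79me2, the dimethylated form of histone H3 that the methyltransferase DOT1L makes, was mapped by chromatin immunoprecipitation and sequencing in cultured mouse spermatogonial stem cells, the germ cells that renew themselves and give rise to sperm. Per the labels' protocols, the cells came from testes of 7-day-old ROSA mice and had grown for 2 months on SNL 76/7 feeder cells, a mouse fibroblast line, in a medium without serum to which GDNF (10 ng/mL) and FGF2 (0.5 ng/mL) had been added. They were then grown for 7 days with 2 µM EPZ5676, a DOT1L inhibitor, or with vehicle, and fixed with 1% formaldehyde for 10 min. The protocols name DMSO as the vehicle, whereas the short descriptions of the control samples name ethanol, and which was used could not be settled here. The protocols name no step that separated the germ cells from the feeder cells before fixation.

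The series has 8 samples in 4 groups of 2, namely H3K79me2 and input chromatin from control cultures and from EPZ5676-treated cultures. The analysis rests on 2 peak lists, 1 for the control and 1 for EPZ5676, each recorded under replicate 1 of its H3K79me2 group. Whether each list was called on 1 replicate or on pooled replicates, and whether the inputs served as background, is not given in the sources used here. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Trimmomatic and deepTools were used, with the mm10 genome build. The aligner and the peak caller are not given in the sources used here.

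Each list has 9 columns without a header, in the layout of broad peak calls. The score the authors deposited for each peak is the whole part of 10 times the −log10 q-value in all but 4 control peaks. The fold enrichment in the deposited lists is the ratio of signal to background of that peak. The deposited −log10 p-value and −log10 q-value columns are the authors' own. The lowest deposited −log10 q was 1.05 in the control list and 1.04 in the EPZ5676 list, and the lowest −log10 p was 2.36 and 4.03. Scores, folds, p and q are the authors' values and were used only to describe, rank or filter peaks, with 1 added alternative that applied the p-value floor of the EPZ5676 list to the control list. No column of per-sample values was left unmapped (0 columns).

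Read depth is not part of the peak lists, so the depth of each sample is unknown here. With 1 list per condition there is no spread between replicates, and no test between conditions was made. Exact Clopper-Pearson 95% intervals on shares of peaks cover the sampling of peaks only, and neighbouring peaks are not independent.

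Peaks of both lists were compared by overlap of at least 1 bp. The overlap was set beside 1000 random placements of the EPZ5676 peaks on their own chromosomes, either anywhere or inside protein-coding genes, and beside 100 placements for the share of control peaks overlapped, for which 1000 had been planned. Genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 also names, with 21883 protein-coding genes on chromosomes 1 to 19, X and Y. The table gives no strand, so the gene starts needed for the rule planned before the data were examined (a window at the start of the gene) could not be placed. The whole gene span, set down beforehand as another choice, took its place, and a gene counted as marked when a peak covered at least 1 bp of its span. For the same reason the planned split of peaks into promoters, gene starts and gene bodies was reduced to inside and outside protein-coding gene spans. A peak was assigned to every gene whose span it overlapped.

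Before the data were examined, 19 gene lists with 319 different genes were fixed, of which 318 were in the table (Gcna was not). They covered the 4 Hox clusters, undifferentiated spermatogonia, spermatogonial differentiation, germ cell identity, meiosis, spermiogenesis, the DOT1L and super elongation complexes, histone lysine methyltransferases, GDNF and FGF signalling, the cell cycle, the p53 pathway and cell death, cytosolic ribosomal proteins, pluripotency, testis somatic cells, fibroblast feeder cells and genes of unrelated tissues. For each list, the number of members with a control peak was set beside 10000 random lists whose members were drawn from the 50 genes nearest in length. The number of control-marked members that also had an EPZ5676 peak was set beside 10000 random lists drawn from the 50 control-marked genes nearest in control-covered length and gene length. These percentages describe the 2 lists and are not tests of the treatment. Another 3 lists were added after a first look at the data and appear only in the closing part and in the plot of gene lists.

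Named genes followed a rule fixed beforehand: Dot1l and every Hox gene with a peak, the 10 genes with the longest control coverage and no EPZ5676 peak, the 10 with the longest EPZ5676 coverage, the 5 with the longest EPZ5676 coverage and no control peak, and from each fixed list the 2 members with the longest and the 2 with the shortest control coverage. Other members are named where a count of 5 or fewer called for it or where a member stood out, and those were chosen after their values were seen.

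The overlap code was tested on simulated data: covered lengths of 10000 simulated intervals differed from bedtools 2.31.1 in 0 cases. For the comparison of control and EPZ5676 lists over 11525 genes, EPZ5676 marks were simulated from control coverage, each gene on its own. With lists of 30 genes, 1 of 40 random lists and 39 of 40 lists planted with a rate raised by 30 percentage points were called above their matched lists. Shorter lists, low counts and neighbouring genes that share a peak were not checked in this way. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives changed the minimum overlap, the score, the length of the control list, the joining of nearby peaks, the minimum width, the covered length a gene needed and the set of genes. Windows around transcription start sites were not run for want of strand. Added after the data were seen were the shared p-value floor, genes that overlap no other protein-coding gene, genes on autosomes, and EPZ5676 peaks that overlap a control peak.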

Results

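H3K79me2 peaks were compared between cultured mouse spermatogonial stem cells grown with 2 µM EPZ5676, an inhibitor of the H3K79 methyltransferase DOT1L, and control cultures, after 7 days. The series concerns the part DOT1L plays in the self-renewal of germline stem cells, and the comparison asks where the mark remained under the inhibitor. Each condition had 2 H3K79me2 samples and 2 inputs but 1 peak list, so no value has a replicate error and no test between conditions was possible. The read depth of the samples is unknown here.

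In control cells, most H3K79me2 peaks lay in genes, and most of them, the narrow ones above all, overlapped no peak after EPZ5676. The control list held 47774 peaks covering 168.9 Mb, and the EPZ5676 list held 9182 peaks covering 4.64 Mb, a ratio of 5.20 in peak number and 36.4 in covered length. The widest control peak ran 175983 bp over Igf1r, the receptor for insulin-like growth factor (chromosome 7, 67952708 to 68128690, mm10). The widest EPZ5676 peak ran 8867 bp inside Parva, which encodes a focal adhesion protein (chromosome 7, 112435093 to 112443959). The median width was 1102 bp in the control (quartiles 498 and 3135 bp) and 402 bp after EPZ5676 (256 and 583 bp). Protein-coding gene spans make up 38.2% of the sequence considered and held 94.8% of the control-covered length and 78.4% of the EPZ5676-covered length. The lists differ in their lowest −log10 p, and with the control list held to the floor of the EPZ5676 list it had 17910 peaks, 1.95 times the EPZ5676 number, and 29.8 times its covered length.

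The control peaks of highest score lay over Rnf126, a ubiquitin ligase gene (fold enrichment 9.85), Kpna3, an importin gene, Aen, a p53-induced nuclease gene (9.93), Fbl, the gene of the nucleolar protein fibrillarin (9.42), and Ski, a transcriptional corepressor gene (9.81). Of these 5 peaks, all but the one at Aen overlapped an EPZ5676 peak. Of all control peaks, 3095 of 47774 overlapped an EPZ5676 peak, or 6.48% (95% interval 6.26 to 6.70%), against a mean of 1.47% over 100 random placements. Of the control-covered bases, 1.72% were still covered. In the other direction, 5119 of 9182 EPZ5676 peaks overlapped a control peak, or 55.8% (54.7 to 56.8%), against a mean of 7.79% for random placement anywhere and 18.0% for random placement in protein-coding genes. The remaining 4063 EPZ5676 peaks lay in protein-coding genes in 40.6% of cases, with a mean of 40.4% (95% of placements within 38.9 to 41.9%) at random. Those placements could fall inside control peaks, 94.8% of whose length lies in genes, whereas the 4063 peaks by definition do not. The near-equal shares therefore do not show that these peaks lie at random. With overlap of at least 50% of the peak, 0.798% of control peaks were overlapped.

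Control peaks that overlapped an EPZ5676 peak were wide and strongly enriched. Their median width was 9042 bp and their median fold enrichment 3.26, against 1013 bp and 2.28 for the others (area under the ROC curve 0.802 for width and 0.758 for fold). An EPZ5676 peak lay on 1.65% of control peaks under 500 bp, on 10.6% of those of 5 to 10 kb and on 52.4% of those over 20 kb. A wider peak offers more room for an overlap, and the share of covered length that stayed covered ranged only from 1.10% under 500 bp to 2.38% over 20 kb. Even so, the wide domains over Auts2 (130030 bp), Zbtb16 (127978 bp) and Bnc2 (119350 bp) had no overlapping EPZ5676 peak.

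**Figure D1:**
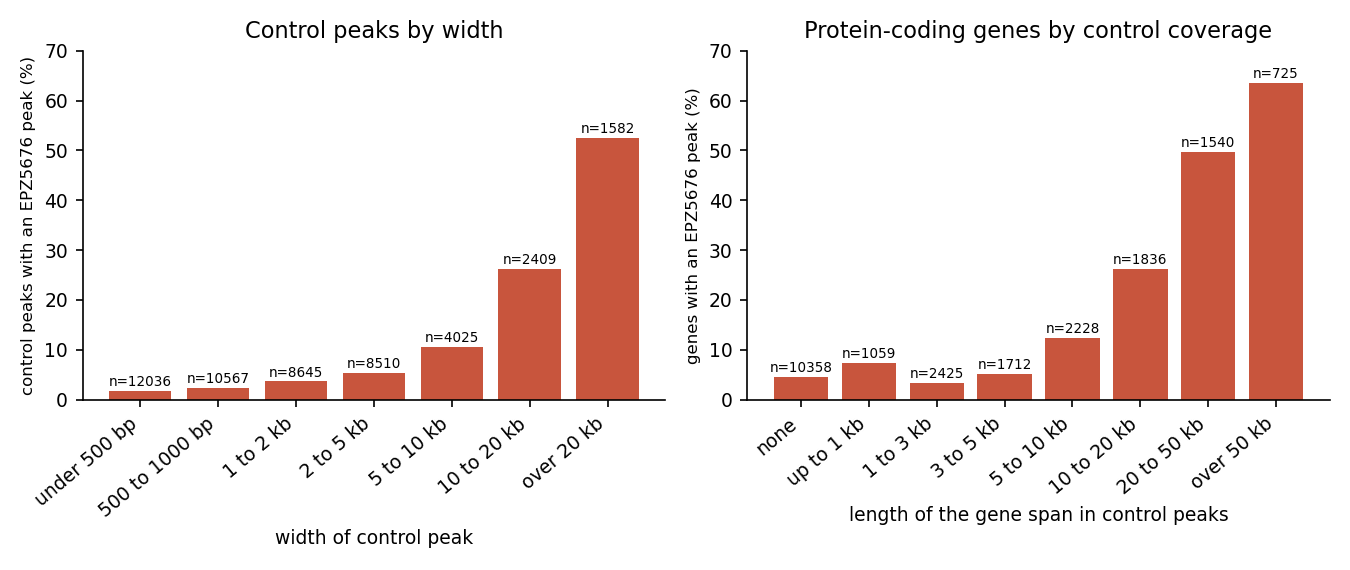
Share of control peaks that overlap an EPZ5676 peak by width of the control peak (left) and share of protein-coding genes with an EPZ5676 peak by the length of their span in control peaks (right), both in percent, with the number of peaks or genes over each bar. The share was 1.65% for peaks under 500 bp and 52.4% for peaks over 20 kb, and 4.53% for genes without a control peak and 63.6% for genes with over 50 kb covered.

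Counted by gene, 11525 of 21883 protein-coding genes had a control peak (52.7%) and 2696 had an EPZ5676 peak (12.3%). Both lists marked 2227 genes, or 19.3% of the control-marked genes, while 9298 were marked in the control only and 469 after EPZ5676 only. In the genes marked in both, the median covered length was 22448 bp of the span in the control (44.0%) and 812 bp after EPZ5676 (1.42%), and 68 genes had the longer coverage after EPZ5676. An EPZ5676 peak lay on 7.27% of genes with up to 1 kb of control coverage, 3.26% with 1 to 3 kb, 5.08% with 3 to 5 kb and 63.6% with over 50 kb. Gene length differed as well, with a median of 9361 bp for 1 to 3 kb covered and 142601 bp for over 50 kb. Dot1l itself, which encodes the inhibited enzyme (chromosome 10, 80755101 to 80795461), had 5 control peaks over 15445 bp with a highest fold enrichment of 9.06, and 1 EPZ5676 peak of 855 bp. With peaks of at least 1000 bp, 528 genes had an EPZ5676 peak.

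The 10 genes with the longest control coverage and no EPZ5676 peak were led by Auts2, whose product acts with Polycomb proteins (387018 bp covered), Bnc2, a zinc finger gene (300052 bp), Msi2, an RNA-binding protein gene (252549 bp), Aff3, of the AF4 family of elongation factors (241919 bp), and Foxn3, a forkhead gene (225206 bp). Snd1 (204589 bp), St6galnac3 (189840 bp), Pitpnc1 (179986 bp), Zbtb16 (168701 bp) and Gse1 (165911 bp) completed the list. The spans of Foxn3, Snd1, Zbtb16 and Gse1 overlap another protein-coding gene, so part of their coverage cannot be assigned to them alone.

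Genes of undifferentiated spermatogonia were marked in the control and mostly without a peak after EPZ5676. Of 25 members, 19 had a control peak, where random lists of the same gene lengths had a mean of 13.4 and 1.24% had at least as many. Of those 19, 2 had an EPZ5676 peak, against a mean of 4.27 in matched lists, and 10.8% of matched lists had as few. Zbtb16, which encodes the self-renewal factor PLZF (chromosome 9, 48651797 to 48836225), was covered over 91.5% of its span in the control and had no EPZ5676 peak. Gfra1, the GDNF co-receptor gene (chromosome 19, 58235581 to 58455946), had 37 control peaks over 96347 bp and no EPZ5676 peak, although its span overlaps another gene. The 2 with both peaks were Foxo1, a forkhead factor of self-renewal (78994 bp in the control, 1568 bp after EPZ5676), and Itga6, an integrin gene (30963 and 762 bp). Eomes and Pax7, transcription factor genes, had no peak in either list, and Shisa6 had only an EPZ5676 peak (1039 bp).

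Differentiation and other germline genes followed with few or no EPZ5676 peaks. Of 13 genes of spermatogonial differentiation, 12 were marked in the control, among them Kit, the receptor of differentiating spermatogonia (23890 bp), and Sox3 (254 bp), while Esx1 was not. Dnmt3a, a DNA methyltransferase gene, was the only one of the 12 with an EPZ5676 peak (29663 bp in the control, 152 bp after EPZ5676), where matched lists had a mean of 1.95 and 36.8% had as few. Sox3 and Rhox13 lie on X, where the EPZ5676 list has no peak, and with autosomal genes alone 1 of 10 had an EPZ5676 peak and 35.9% of matched lists had as few. Of 11 germ cell identity genes, 10 were marked, among them Mael (24308 bp) and Tex15 (23643 bp), genes of transposon silencing, and Dnd1 (610 bp), an RNA-binding protein gene, but not Dppa3. None of the 10 had an EPZ5676 peak, against a mean of 1.87 in matched lists, of which 9.72% also had 0. Of 17 meiosis genes, 15 were marked, led by Sycp1, of the synaptonemal complex (28017 bp), and Stag3, a meiotic cohesin gene (8505 bp), and not Meiob or Spata22. None of the 15 had an EPZ5676 peak, with a mean of 1.06 in matched lists, of which 29.4% also had 0. Of 13 spermiogenesis genes, which act after meiosis, only Gapdhs was marked in the control (2665 bp, overlapping another gene). Acrv1, Akap4 and Catsper1 had no peak in either list, and Odf1 had only an EPZ5676 peak (278 bp). Of 11 pluripotency genes, 7 were marked in the control, led by Lin28a (13755 bp) and Sall4 (11609 bp), and none had an EPZ5676 peak, with a mean of 0.523 in matched lists, of which 55.5% also had 0. Nanog, Esrrb, Zfp42 and Prdm14 were the 4 without a peak in the control.

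The Hox clusters differed from one another in the control and had no EPZ5676 peak. All 10 HoxB genes were marked, where random lists of the same gene lengths had a mean of 4.24 and 0% had 10. Genes of a cluster lie side by side and can share a peak, whereas random lists draw each gene on its own. The percentages for HoxB and HoxD may therefore overstate how unusual these clusters are. Peaks covered 100% of Hoxb13, Hoxb5, Hoxb4 and Hoxb2, 99.8% of Hoxb6, 89.2% of Hoxb7, 87.1% of Hoxb3, 80.5% of Hoxb9, 67.4% of Hoxb8 and 18.7% of Hoxb1. The cluster runs from 96194316 to 96368254 on chromosome 11. Of 9 HoxC genes, 5 were marked, with 2336 bp at Hoxc9, 1914 bp at Hoxc10, 1877 bp at Hoxc13, 1158 bp at Hoxc6 and 1145 bp at Hoxc4, and Hoxc5, Hoxc8, Hoxc11 and Hoxc12 were not. Of 11 HoxA genes, 3 were marked, among them Hoxa10 over 1068 bp and Hoxa11 over 693 bp, with no peak at Hoxa2 or Hoxa13. None of the 9 HoxD genes was marked, including Hoxd1, Hoxd10, Hoxd11 and Hoxd12, where 0.58% of random lists had 0. Of the 18 Hox genes marked in the control, the matched lists had means of 0.878 (HoxB), 0.0197 (HoxC) and 0.0628 (HoxA) with an EPZ5676 peak, so the 0 seen carries little weight. At the p-value floor of the EPZ5676 list, 2 HoxC genes and 0 HoxA genes were marked in the control.

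**Figure D2:**
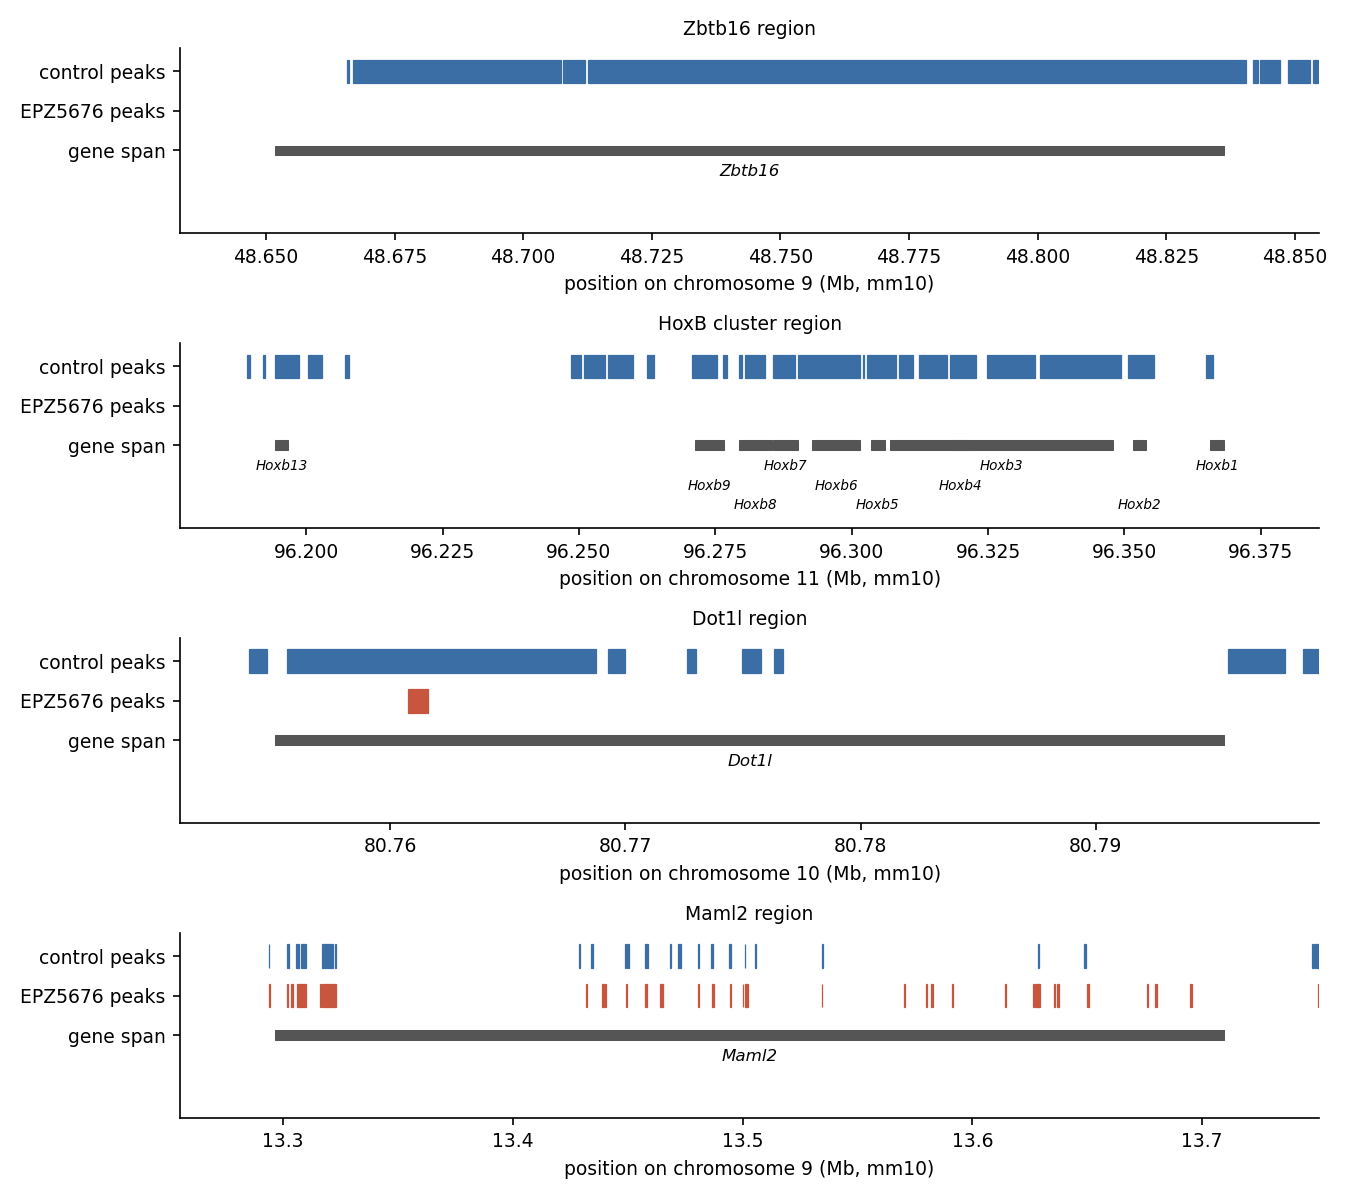
Control peaks (blue) and EPZ5676 peaks (red) over 4 regions, with gene spans in grey and position in Mb (mm10) on the horizontal axis. Zbtb16 and the HoxB cluster have no EPZ5676 peak, Dot1l has 1 of 855 bp, and Maml2 has peaks in both lists, over 19629 bp in the control and 26739 bp after EPZ5676.

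Genes of the DOT1L complex and of the super elongation complex, the latter of which releases paused RNA polymerase, were all marked in the control. Most of them had a short EPZ5676 peak. Of 12 members, 12 were marked and 8 of those had an EPZ5676 peak, against a mean of 4.97 in matched lists, of which 5.43% had at least as many. Aff1 had 101607 bp in the control and 3973 bp after EPZ5676. Mllt10 (101183 bp, overlapping another gene), Mllt1 (36219 bp), Mllt6 (6038 bp) and Cdk9 (5769 bp) had no EPZ5676 peak. With at least 500 bp of the gene covered, 5 of the 12 had EPZ5676 coverage, and 34.4% of matched lists had at least as many (mean 3.90). With genes overlapping no other gene it was 8 of 11, and 2.24% of matched lists had at least as many, so the standing of this list depended on the choice. All 21 histone lysine methyltransferase genes were marked, and 9 had an EPZ5676 peak, with a mean of 7.08 in matched lists. Kmt2c had 92123 bp in the control and 1333 bp after EPZ5676, and Ehmt1 had 81344 and 1490 bp. The X-linked Suv39h1 (3815 bp) and Kmt5c (870 bp) had no EPZ5676 peak.

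All 23 genes of GDNF and FGF signalling, the pathways of the growth factors in the medium, were marked in the control. An EPZ5676 peak lay on 11 of them, against a mean of 8.36 in matched lists, of which 14.2% had at least as many. Fyn, a Src-family kinase gene, had 141675 bp in the control and 147 bp after EPZ5676, and Fgfr3 (1171 bp) and Mapk3 (2019 bp) had control peaks only. Fgfr2 stood apart, with 20021 bp in the control and 11747 bp after EPZ5676, as did Lyn with 5277 and 4410 bp; both were chosen after their values were seen. With at least 500 bp covered, 7 of the 23 had EPZ5676 coverage, and 45.8% of matched lists had at least as many (mean 6.35). With genes overlapping no other gene it was 10 of 19, and 3.39% of matched lists had at least as many (mean 6.23).

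Cell cycle, cell death and ribosomal protein genes were marked in the control almost throughout. Of 26 cell cycle genes, 25 were marked, led by Cdk6 (71863 bp) and Ccnd3 (68412 bp, overlapping another gene) and ending with Pcna (1946 bp), while Myc was not. Of the 25, 4 had an EPZ5676 peak, namely Cdk1 (848 bp), Mki67 (932 bp), Cdk6 (465 bp) and Aurka (398 bp), against a mean of 2.30 in matched lists, and 2 had at least 500 bp covered. Of 15 genes of the p53 pathway and cell death, 14 were marked, including Bcl2l1 (51505 bp), Mdm2 (12528 bp) and Fas (2237 bp). An EPZ5676 peak lay on 3 of the 14, Bcl2l1 (1189 bp), Casp8 (2943 bp) and Sesn2 (404 bp), against a mean of 2.01, and Bcl2, without a control peak, had 846 bp after EPZ5676. All 45 cytosolic ribosomal protein genes were marked, from Rpl22 (6455 bp) and Rpl18 (4690 bp) down to Rps23 (976 bp) and Rps6 (932 bp). None had an EPZ5676 peak, with a mean of 0.492 in matched lists.

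Among genes of other cell types, the fibroblast feeder list had more members with both peaks than most matched lists, while too few testis somatic and unrelated-tissue genes were marked for such a comparison. Of 16 genes of fibroblast feeder cells, 9 were marked in the control, close to the mean of 9.66 in random lists. Of the 9, 4 had an EPZ5676 peak, against a mean of 1.14 in matched lists, of which 1.24% had at least as many. These were Twist2 (12557 bp in the control, 2907 bp after EPZ5676) and Prrx1 (11779 and 3583 bp), both mesenchymal transcription factor genes, Fbn1 (10333 and 2141 bp) and Sparc (5565 and 241 bp), both genes of matrix proteins. Col1a1 (2433 bp) and Fn1 (1774 bp) had control peaks only, and Col1a2, Col3a1 and Vim had no peak in either list. At the p-value floor of the EPZ5676 list, 4 members were marked in the control and 2 of those had an EPZ5676 peak. Of 18 genes of testis somatic cells, 5 were marked in the control (Wt1 over 9155 bp, Inhba over 2640 bp, Nr2f2, Inhbb and Amh), against a mean of 10.3 in random lists. None of those 5 had an EPZ5676 peak, with a mean of 0.288 in matched lists; Acta2 and Cldn11 had no peak in either list, and Fshr had only an EPZ5676 peak (179 bp). Of 20 genes of unrelated tissues, 3 were marked in the control, Mbp (1655 bp), Afp (772 bp) and Syn1 (619 bp), none had an EPZ5676 peak (mean 0.257 in matched lists), and Actn3 and Alb had no peak in either list.

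**Figure D3:**
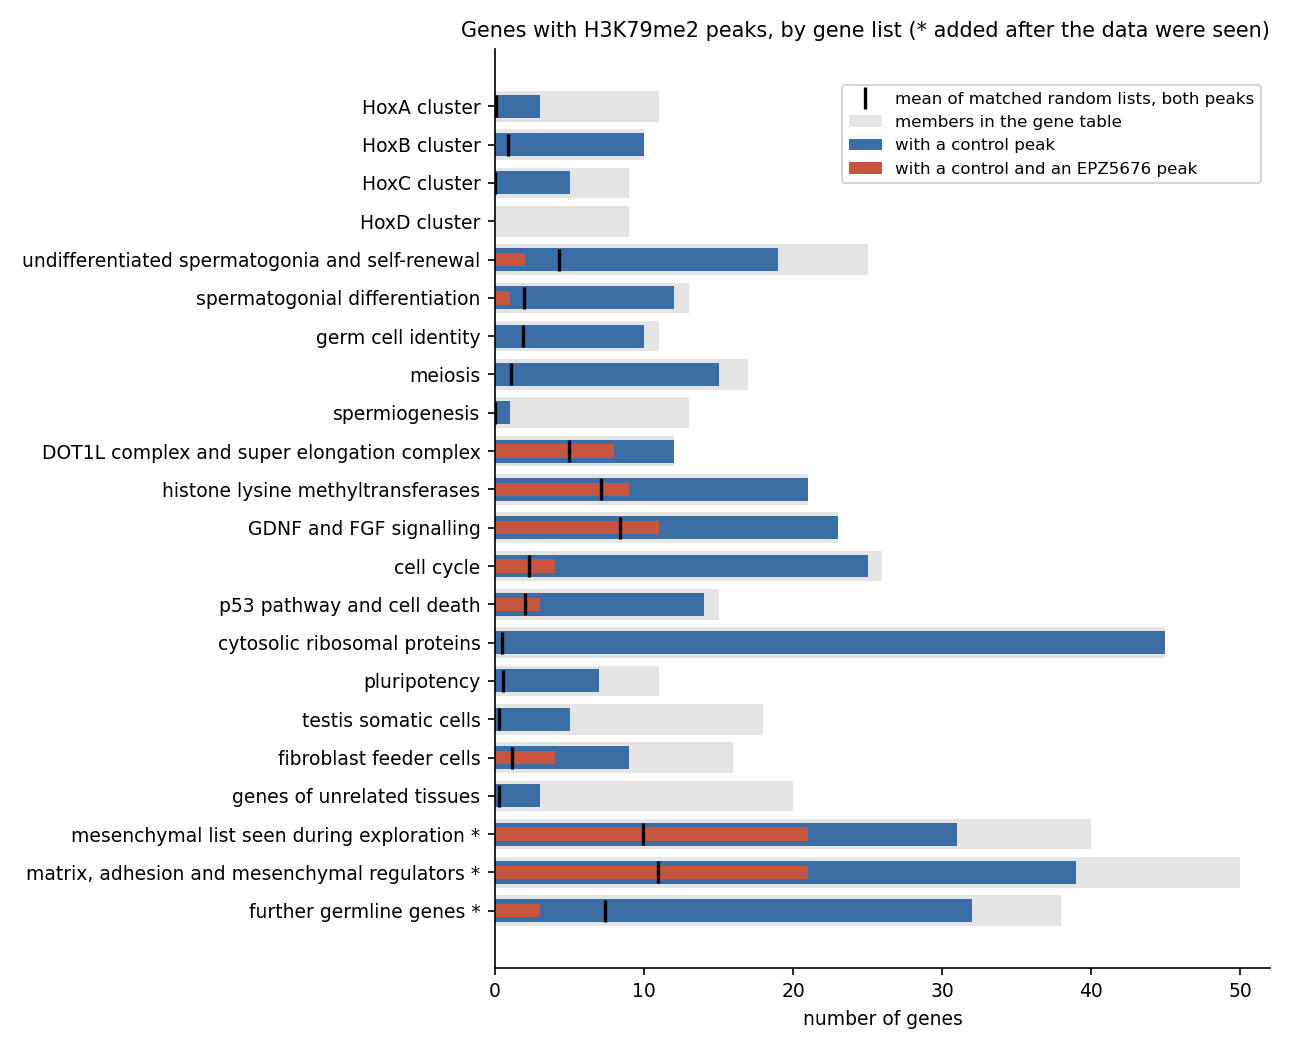
Number of genes per list in the gene table (grey), with a control peak (blue) and with both a control and an EPZ5676 peak (red), with the mean of the matched random lists for both peaks as a black line; an asterisk marks the 3 lists added after the data were seen. Of the fibroblast feeder list 4 of 9 control-marked genes had both peaks (mean 1.14 in matched lists), and of the germ cell identity list 0 of 10 (mean 1.87).

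The 10 genes with the longest EPZ5676 coverage were led by Maml2 and Setbp1. Maml2, a Notch coactivator gene (chromosome 9, 13296561 to 13709533), had 26739 bp after EPZ5676 and 19629 bp in the control. Setbp1, which encodes a SET-binding protein (chromosome 18, 78750378 to 79110444), had 25709 and 25665 bp. Nrp1, the neuropilin-1 gene, had 22455 bp after EPZ5676 and 28969 bp in the control, and Egfr, the epidermal growth factor receptor gene, had 16033 and 20402 bp. Longer control coverage was found for Pakap (22287 bp after EPZ5676, 137289 bp in the control), Lhfp (21379 and 51732 bp), Cald1, the gene of actin-binding caldesmon (18641 and 44512 bp), Parva (16320 and 62270 bp), Trio (16132 and 117867 bp), and Samd4 (15202 and 86105 bp). Among genes without a control peak, the longest EPZ5676 coverage was at Cacnb2, a calcium channel subunit gene (3348 bp), Galnt18 (3095 bp), Lmo7 (2817 bp), Ppargc1a, a coactivator gene of mitochondrial biogenesis (2785 bp), and Ntf3, the neurotrophin-3 gene (2687 bp). These lengths were only 0.421% (Ppargc1a) to 4.11% (Ntf3) of the gene spans. The highest −log10 q per gene ranged from 1.84 (Ntf3) to 2.30 (Cacnb2).

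By chromosome, the EPZ5676 list held no peak on X or Y. The control list had 975 peaks on X, among them the one at Suv39h1, and 32 on Y. On each autosome between 4.89% (chromosome 19) and 10.1% (chromosome 3) of control peaks overlapped an EPZ5676 peak, and 6.62% did over all 19 autosomes. The EPZ5676 list had 2.87 (chromosome 12) to 4.65 (chromosome 15) peaks per Mb on the autosomes. The control list had 5.71 peaks per Mb on X and 19.2 over the autosomes. Median width and fold enrichment of the X control peaks were 999 bp and 2.31.

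**Figure D4:**
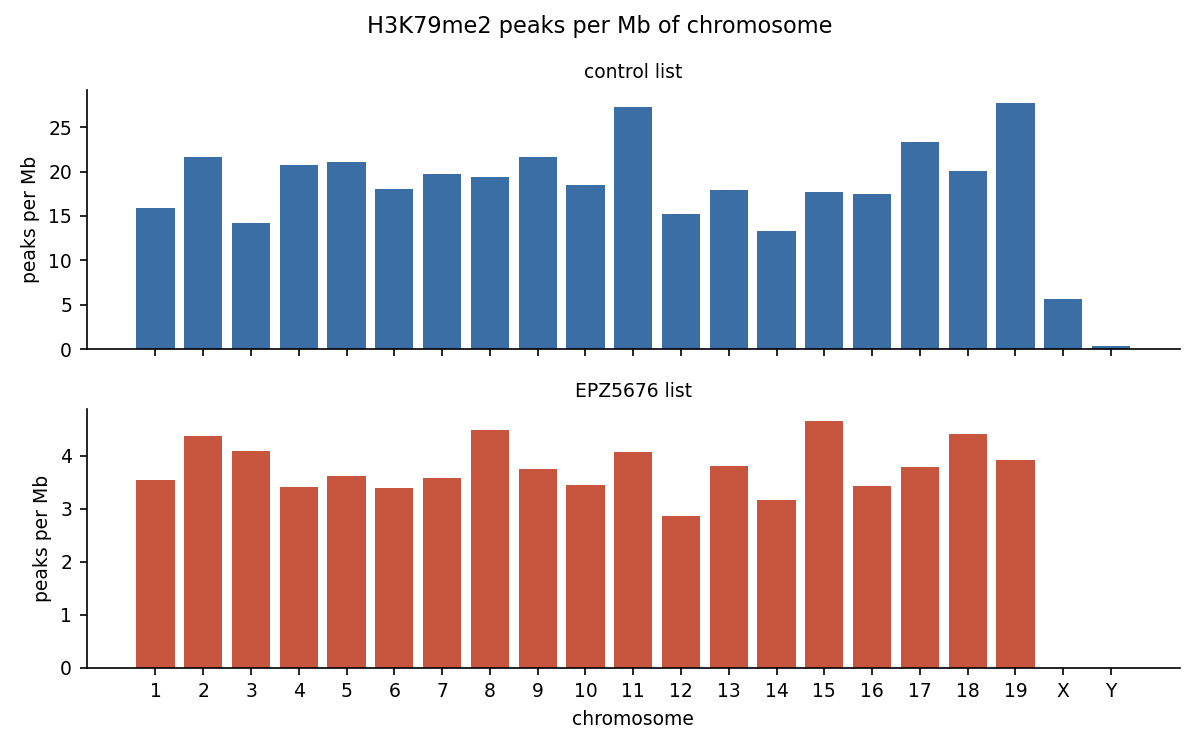
Peaks per Mb of each chromosome in the control list (top) and the EPZ5676 list (bottom), on separate vertical scales that start at 0. Autosomes carry 2.87 to 4.65 EPZ5676 peaks per Mb, and X and Y carry 0, where the control has 5.71 peaks per Mb on X.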

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

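The p-value floor, the genes that overlap no other gene, the autosomal genes and the EPZ5676 peaks that overlap a control peak were chosen as alternatives after the data were seen; the others were planned. No paired analysis was possible because each condition has 1 peak list, and for the same reason leaving out a replicate was not an option. Windows around transcription start sites, 1 kb on each side or at any transcript, were not run, since the gene table has no strand. In every alternative but the control list held to the EPZ5676 number of peaks, the control list had more peaks, and in all of them it covered more Mb. Moves that follow from fewer, wider or joined peaks come from the alternatives' own construction; the cause of the others was not tested. Read depth, which is unknown, limits all of these values.

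With overlap of at least 50% of the peak, 0.798% of control peaks were overlapped by EPZ5676 peaks and 53.3% of EPZ5676 peaks overlapped control peaks, and with reciprocal overlap of at least 50% the shares were 0.536% and 2.79%. With only peaks at or above the median control score, there were 25198 control and 452 EPZ5676 peaks (0.230 Mb), 0.941% of control peaks were overlapped, 0.103% of the control-covered length stayed covered, and 307 genes had an EPZ5676 peak, 267 of them with both, or 2.55% of control-marked genes. With the 9182 control peaks of highest score, the control covered 107.9 Mb, 19.03% of control peaks were overlapped, 38.4% of EPZ5676 peaks overlapped them and 22.6% of control-marked genes had an EPZ5676 peak. With peaks joined under 1 kb, 8.73% and 53.3% of peaks overlapped. With peaks joined under 5 kb, there were 15947 control peaks, EPZ5676 peaks covered 9.08 Mb, 14.7% and 47.8% of peaks overlapped, and 3.14% of the control length stayed covered. With peaks of at least 1000 bp, there were 25182 control and 777 EPZ5676 peaks (1.21 Mb), 2.29% and 84.4% overlapped, 0.638% of the length stayed covered, and 528 genes had an EPZ5676 peak, 510 of them with both (4.90% of control-marked genes). Restricting to chromosomes 1 to 19, X and Y removed no peak.

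With at least 500 bp of a gene covered, 1700 genes had EPZ5676 coverage and 13.5% of control-marked genes did, with 5 genes of the DOT1L and super elongation complexes, 7 of GDNF and FGF signalling, 2 of the cell cycle and 0 of spermatogonial differentiation. Over all annotated genes the share was 16.4%. At the p-value floor of the EPZ5676 list there were 17910 control peaks, 12.1% of them overlapped, 44.7% of EPZ5676 peaks overlapped them, and 20.7% of control-marked genes had an EPZ5676 peak. At that floor the control marked 0 HoxA, 2 HoxC, 4 pluripotency, 1 testis somatic, 0 unrelated-tissue and 4 fibroblast feeder genes (2 of them with an EPZ5676 peak), and 20 of the mesenchymal list put together during exploration. With genes that overlap no other protein-coding gene, the share was 20.4%, and 0 of 12 spermiogenesis and 16 of 17 cell cycle genes were marked in the control. With only EPZ5676 peaks that overlap a control peak the share was 18.2%. With autosomal genes only, no value moved. The other 265 values stayed within the 95% interval of the reported share or, for counts and lengths, within 1.5 times the reported value, against 56 that did not. Part of the 265 could not move, such as a count of 0 under a narrower choice. The same holds for EPZ5676 counts when only the control list was cut, and where no peak was removed. The number that stayed is therefore no measure of robustness.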

Other observations

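Chosen after their results were seen were the tests on the fixed fibroblast list, the abundant fibroblast genes, the width of X peaks, the removal of X and Y, the p-value floor, the read number and the background calls; the tests on the second mesenchymal list, the further germline genes, the covered length of mesenchymal genes and the X share outside genes were set down before their results were seen.

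Several genes of matrix, adhesion and mesenchymal regulation had long EPZ5676 coverage. A list of 40 such genes was put together during exploration, while their peaks were being seen, so its number of EPZ5676 peaks tests nothing. It included Cdh11, a cadherin gene (20543 bp in the control, 9756 bp after EPZ5676), Tead1, a Hippo pathway factor gene (164589 and 9795 bp), Col6a3, a collagen gene (12562 and 5797 bp), and Cd44, a hyaluronan receptor gene (14483 and 4766 bp). The highest EPZ5676 scores were at a pair of peaks in D5Ertd579e on chromosome 5, from 36661013 to 36661584 with a fold enrichment of 5.22, and from 36630498 to 36630795 with 3.46. Of the histone methyltransferase genes, Nsd2 had the longest EPZ5676 coverage (6370 bp, and 37092 bp in the control). All genes named in this paragraph were chosen after their values were seen.

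EPZ5676 peaks lay on mesenchymal genes more often than on matched genes, and a candidate explanation is H3K79me2 of the fibroblast feeder cells, which the labels' protocols name without naming a step that removed them. Feeder cells still present at fixation would have been exposed to EPZ5676 as well. Whether they kept the mark under the inhibitor was not tested. On the fixed fibroblast list 1.24% of matched lists had at least as many control-marked members with an EPZ5676 peak, and on a second list of 50 mesenchymal genes 0.01% did (21 of 39, among them Ltbp1, Zeb1, Tcf4 and Osmr). On 38 further germline genes, 3 of 32 had an EPZ5676 peak (Mybl1, Igf2bp1 and Celf4) against a mean of 7.36, and 2.49% of matched lists had as few, with 3.82% at the p-value floor, 3.52% with EPZ5676 peaks overlapping control peaks, 2.64% on autosomes, 5.06% with at least 500 bp covered (2 against 5.45) and 6.02% with genes overlapping no other gene (3 against 6.38), around the 5% limit set beforehand, while on the 4 fixed lists from undifferentiated spermatogonia to meiosis 10.8%, 36.8%, 9.72% and 29.4% had as few. Longer control coverage and longer genes do not account for the mesenchymal side, since genes matched on both gave 10.9 members where 21 were seen in the second list. Among Col1a1, Col1a2, Col3a1, Fn1, Vim and Sparc, whose transcripts are abundant in fibroblasts, only Sparc had an EPZ5676 peak (16.7%, 95% interval 0.421 to 64.1%, against 48.0% of the second list). Col1a2, Col3a1 and Vim had no peak in the control either. The interval includes the 48.0%, and the 6 genes are not matched on control coverage or length, so they decide nothing about the feeder cells. They were picked after their values were seen, and the test on the fixed fibroblast list was likewise chosen after its result was seen. An effect of the inhibitor on mesenchymal genes of the germ cells, whose expression was not measured here, stays open as untested.

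The EPZ5676 list had no peak on X or Y, and weaker or narrower X control peaks do not account for it: autosomal control peaks matched on width and fold enrichment predicted 40.8 X peaks with an EPZ5676 peak, where a count of 0 allows 3. A lower read depth over a single X in male cells remains a candidate, since X held 1.40% of the control peaks outside protein-coding genes (95% interval 1.09 to 1.76%) and 7.48% of the sequence there. A scarcity of marked sequence on X would give the same low share, so that value does not single out depth. Removal of X and Y during processing stays open. The EPZ5676 peaks are numbered with 0 numbers missing, but X and Y come last in the order of the control list. If the EPZ5676 list had the same order, a loss at the end would leave no gap. By its share of sequence X would have held 257 of the EPZ5676 peaks that overlap no control peak. That number assumes an even spread over the sequence, which was not shown. Control peaks were sparser on X (5.71 per Mb) than over the autosomes (19.2 per Mb), so the number may be too high. No biological explanation was tested.

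The EPZ5676 list covered far less sequence, as an inhibitor of DOT1L would give. Its lowest −log10 p was 4.03 against 2.36 in the control, while the lowest −log10 q was alike (1.04 and 1.05). With the control list held to the same p-value floor, the covered lengths still differed 29.8 times. Only whole peaks were dropped there and the others kept their full width, so this value does not settle what a threshold does to length. Of the EPZ5676 peaks, 55.8% overlapped control peaks, and at most 19.2% did in any random placement inside protein-coding genes. The EPZ5676 list was thus not made only of calls spread evenly over those genes. Background calls that recur at the same places in both lists were not tested. Fewer reads in the EPZ5676 libraries cannot be told apart from loss of the mark, because the lists hold no read numbers. Of the 478 control peaks in the top 1% by fold, 64.0% (95% interval 59.5 to 68.3%) had an EPZ5676 peak against 5.90% of the others, an order by fold that both a lower depth and a partial loss of the mark could give. The top peaks and the others were not matched on width, and a wider peak offers more room for an overlap. In those 478 peaks 5.28% of the covered length stayed covered. The EPZ5676 list had a median fold enrichment of 2.75 and −log10 q of 1.43, against 2.30 and 2.17 in the control. Fewer reads could give a higher fold at a lower significance, which was not tested. The stricter p-value floor could raise the fold. It drops the least significant peaks, so by itself it would not lower the significance.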
